A study of Homo sapiens with 36 samples.

How the data were processed

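Jurkat cells, an established line from a human T cell acute lymphoblastic leukaemia (T-ALL), carried TAL1 fused to the FKBP12 tag and were exposed to DMSO or to dTAG-13. Total RNA was taken after 1, 2, 4, 6, 8, 16, 24, 48 and 72 h, so that 36 libraries fall into 18 groups of 2. Groups, times and replicate numbers were read from the sample titles, per the labels; the treatment protocol in the labels does not list the 6 h time, which the titles and the design text of the series do. Each time has DMSO libraries of its own, and no comparison shares controls with another. Per the labels, RNA was extracted with a column kit that keeps small RNA, strand-specific libraries were built, and paired ends were sequenced on a DNBSEQ instrument. Nothing in the labels says whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

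Per the submitters' processing notes, STAR 2.5.2a, featureCounts (version not given in the sources used here) and DESeq2 1.12.4 were used with genome build hg19. The annotation release and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of a gene cannot be told from those of an antisense or overlapping gene. C11orf74, MIR4435-1HG and BCL2L11 are given as uncertain for this reason, and the other genes were not each examined for it. The authors deposited 9 tables of whole-number counts per gene, 1 for each time, with 63677 gene identifiers and 4 libraries in each. The authors also deposited 9 tables of their own comparison of dTAG-13 with DMSO, which hold a log2 fold change with its standard error and an adjusted p-value per gene. Gene symbols were taken from the deposited 1 h comparison table, which pairs each identifier with a symbol. The reference annotation used here, GENCODE v29, is on another build (GRCh38), so it served only for the order of neighbouring genes and for overlaps of exons, and no coordinates are given.

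All tests ran on the deposited counts with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Total counts per library ran from 19354186 to 20473104. The 36 libraries entered 1 edgeR quasi-likelihood model with 18 groups and robust outlier handling, which leaves 18 residual degrees of freedom. Genes passed filterByExpr on the 18 groups (minimum count 10), which kept 16834 of 63677 genes. Library sizes were scaled by TMM. For each time dTAG-13 was compared with DMSO, 2 libraries against 2. The mean of the 9 contrasts, the 8 differences between the 9 contrasts (the interaction of treatment and time) and the mean of the 24, 48 and 72 h contrasts minus the mean of the 2, 4, 6 and 8 h contrasts (late minus early) were tested in the same model. Every adjusted p in the text comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment within a comparison unless a sentence names another tool, and a gene was called at an adjusted p below 0.05 with no minimum fold. Fold changes are log2 of dTAG-13 over DMSO, given with their standard errors (SE). CPM values are scaled by TMM and given as mean ± SD (n = 2).

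Of 32 gene lists, 30 had at least 3 genes past the filter and were tested with camera at a preset correlation of 0.01, adjusted over all lists and the 9 times (270 tests), and separately over the lists for the mean and for late minus early. The lists are the TAL1 core regulatory circuit, reported TAL1-activated genes, the GIMAP family, E proteins with ID and other bHLH factors, T-ALL oncogenic transcription factors, thymocyte differentiation, the T cell receptor complex, NOTCH targets, MYC targets and ribosome biogenesis, S phase, G2 and mitosis, the BCL2 family, p53 targets, immediate early genes, NF-kB targets, interferon response, cholesterol synthesis, integrated stress and unfolded protein response, heat shock, glycolysis and hypoxia, homing and cytokine receptors, the retinoic acid pathway, cereblon ligase with its ligand-induced substrates, the FKBP family, erythroid and megakaryocyte markers, B cell markers, NK and cytotoxic markers, ribosomal proteins, replication-dependent histones and mitochondrial mRNAs. Myeloid markers and epithelial and fibroblast markers each had 2 genes past the filter and were not tested. The design, the lists, the alternatives and the rule for named genes were set before the data were examined, except where the text says otherwise.

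The rule named TAL1 and FKBP1A at every time. At each time it named the 6 largest called rises and the 6 largest called falls with a mean of at least 1 CPM in the higher group and both dTAG-13 libraries beyond both DMSO libraries. For the mean of the 9 times it named the 15 largest called rises and falls with the same direction at 8 or 9 times, and for late minus early the 8 largest in each direction. Members of the lists could also be named, and features with only a clone name count in totals and are not named. Some genes are not reported here.

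The alternatives were median-of-ratios (RLE) scaling, library size with no composition correction, no low-count filter, a minimum of 1 CPM in 4 libraries, DESeq2, the 4 libraries of a time alone, the replicate number as a block, and each library left out in turn. For the lists they were an estimated correlation and fry. Fits with no robust outlier handling and fits without the 16 h libraries were added after the data were seen. The procedure was tested on simulated counts drawn from the real means, library sizes and dispersions with known genes changed. Each simulated gene had 1 mean and 1 dispersion for all 18 groups apart from the known changes. Neither differences between times, such as the 16 h set, nor unequal replicate spread between groups was simulated. The shares below may therefore not hold for the real groups. For a simulated change at 24 h (16491 genes), 38, 72, 94 and 100% of genes changed 1.25, 1.5, 2 and 4-fold were recovered, and 8 of 160 calls were unchanged genes. For a change at all times the mean recovered 84, 98, 100 and 100% (16464 genes, 11 of 202 calls unchanged), and late minus early recovered 44, 76, 96 and 100% of late changes (16492 genes, 4 of 162 calls unchanged).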

Results

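RNA levels were measured in Jurkat cells whose TAL1 was fused to FKBP12. TAL1 is a basic helix-loop-helix transcription factor that is active in many T-ALL cells, and dTAG-13 is a small molecule that links the FKBP12 tag to the cereblon ubiquitin ligase so that the tagged protein is degraded. Cells received dTAG-13 or the solvent DMSO for 1, 2, 4, 6, 8, 16, 24, 48 or 72 h. Each of the 18 groups had 2 libraries. The comparisons ask which transcripts change under dTAG-13 and when. No untagged cells were among the libraries, and the data hold no TAL1 protein levels. Effects of the compound itself therefore cannot be told from those of losing TAL1. The 36 libraries held 19354186 to 20473104 counts each, and 23011 to 24399 genes had at least 1 count. At this depth 16834 genes could be tested, with a common biological coefficient of variation of 5.55%. Mitochondrial transcripts took 7.53 to 10.58% of the counts and ribosomal protein genes 5.11 to 7.66%. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 3.59 to 10.5, the highest in the 48 h DMSO group. The 4 libraries of 16 h stood apart from the rest whatever their treatment: on the first principal component of 9874 genes, which held 38.6% of the variance, they lay at 25.2 to 27.3 and the other 32 libraries at -7.9 to 3.4.

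TAL1 RNA was not called at any time. Its log2 fold change ran from -0.09 at 1 h to 0.08 at 48 h (SE 0.056 and 0.057, adjusted p of 0.77 or more at every time), and over the 9 times it averaged -0.01 (SE 0.019, adjusted p = 0.97). At 72 h TAL1 stood at 159 ± 0.75 CPM in DMSO and 160 ± 5.4 CPM in dTAG-13 (SD, n = 2). FKBP1A, which encodes the cellular FKBP12 protein, averaged -0.04 (SE 0.021, adjusted p = 0.63), with 592 ± 17 CPM in DMSO and 595 ± 19 CPM in dTAG-13 at 72 h. Because dTAG-13 acts on the protein, the TAL1 transcript does not check the labels of the treated libraries.

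At 1 h and 2 h no gene was called. STAT5A and SIX6, which were lower from 4 h on, had log2 fold changes of -0.27 (SE 0.087) and -0.29 (SE 0.075) at 2 h, neither past the threshold (adjusted p = 1 each). With edgeR 330 genes at 1 h and 506 at 2 h had an unadjusted p below 0.05, where 842 are expected by chance. DESeq2 gave 0 for the genes changed at 1 h (154 at an unadjusted p below 0.05) and 0 for the genes changed at 2 h (288). With the 4 libraries of a time fitted alone, edgeR called MALAT1, a nuclear noncoding RNA, lower at 1 h (adjusted p = 0.017), and at 2 h called RAG1 (0.00053), the sterol enzyme gene MSMO1 (0.014) and CDHR1 (0.035) higher. With no low-count filter MSMO1 and CHRNA3 were called higher at 2 h (adjusted p = 0.04 each). These genes are named because their values were seen.

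At 4 h 11 genes were lower and 0 higher. CEBPE, a transcription factor of granulocyte maturation, fell by 1.66 on the log2 scale (SE 0.27, adjusted p = 0.0015), and MYCN, a MYC family transcription factor, fell by 1.26 (SE 0.25, adjusted p = 0.019). STAT5A, which carries cytokine signals to the nucleus, fell by 0.76 (SE 0.088, adjusted p = 1.4e-06). SIX6, a homeobox gene, fell by 0.57 (SE 0.075, adjusted p = 2.3e-05). GIMAP5, a GTPase of lymphocyte survival, fell by 0.45 (SE 0.068, adjusted p = 0.00028). MYB, a transcription factor of blood progenitors and a member of the TAL1 circuit list, fell by 0.31 (SE 0.061, adjusted p = 0.016). For the count of 0 higher genes, 827 genes in either direction had an unadjusted p below 0.05 in edgeR, and DESeq2 called 0 higher and 14 lower. With no low-count filter 2 genes were called higher, with the replicate number as a block 2 and with the 4 libraries of that time alone 5; RAG2 was called in each of these 3 (adjusted p of 0.00015 to 0.00042). The count of 11 became 5, 4, 3 and 2 without DMSO replicate 1, DMSO replicate 2, dTAG-13 replicate 1 and dTAG-13 replicate 2 of that time. STAT5A and SIX6 were called in all 4 of these fits and GIMAP5 in 3 (adjusted p = 0.063 without dTAG-13 replicate 2). MYCN and MYB were called in none (adjusted p up to 0.73 without DMSO replicate 2 and 0.67 without dTAG-13 replicate 1) and CEBPE in the fit without DMSO replicate 1 alone (otherwise up to 0.24).

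Reported TAL1-activated genes had fallen as a list by 4 h, with 1 of 5 called and 3 when adjusted over the list alone, ALDH1A2 and ARID5B among them (median -0.25, camera adjusted p = 3.9e-05; adjusted p = 0.02 with an estimated correlation). Of the 7 GIMAP genes 1 was lower at 4 h and 6 when adjusted over the list alone (median -0.26, camera adjusted p = 5.3e-14; adjusted p = 0.0083 with an estimated correlation). T-ALL oncogenic transcription factors, of which 3 passed the filter, fell at 4 h through MYCN, and through MYCN and LYL1 when adjusted over the list alone (camera adjusted p = 2.2e-06 and, with an estimated correlation, 0.0091). With the preset correlation camera also called ribosomal proteins at 4 h, a check on library composition (adjusted p = 4.1e-19). None of its 85 members was called, and the list was not called with an estimated correlation.

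At 6 h 14 genes were lower and 0 higher, and at 8 h 23 were lower and 3 higher. CEBPE fell at 6 h (-1.93, SE 0.3, adjusted p = 0.00042) and 8 h (-2.33, SE 0.31, adjusted p = 3.8e-05). ZNF521, a zinc finger cofactor of blood progenitors, fell at 6 h (-0.73, SE 0.12, adjusted p = 0.00089) and 8 h (-0.78, SE 0.12, adjusted p = 0.00018). STAT5A fell at both times (-0.72 and -0.74, SE 0.088 and 0.089). MYCN fell at both as well (-1.44, SE 0.27, adjusted p = 0.0049 and -1.18, SE 0.27, adjusted p = 0.046). C10orf107, the open reading frame next to ARID5B, fell by 0.65 at 6 h (SE 0.12, adjusted p = 0.0074). ALDH1A2, an enzyme that makes retinoic acid, was first called at 8 h (-0.56, SE 0.098, adjusted p = 0.0058). The progenitor surface gene CD34 (-0.87, SE 0.18, adjusted p = 0.016) and the T cell ligand gene CD40LG (-0.66, SE 0.13, adjusted p = 0.028) fell at 8 h. The 3 higher genes at 8 h were TCP11L2 (1.29, SE 0.27, adjusted p = 0.019), the recombination gene SWI5 (0.54, SE 0.11, adjusted p = 0.017) and PRR5, a partner of the mTOR kinase (0.54, SE 0.12, adjusted p = 0.035).

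For the 0 higher genes at 6 h, 622 genes in either direction had an unadjusted p below 0.05 in edgeR, and DESeq2 called 2 genes higher and 22 lower. With no low-count filter 5 were higher, with the replicate number as a block 4, with the 4 libraries of that time alone 10, and without dTAG-13 replicate 2 of that time 1. The 6 h count of 14 became 9 without DMSO replicate 1, 5 without DMSO replicate 2 and 5 without dTAG-13 replicate 1. At 8 h the count of 26 became 9 without DMSO replicate 1, 7 without dTAG-13 replicate 1 and 10 without dTAG-13 replicate 2. STAT5A was called in all of these fits at both times. MYCN lost its 6 h call without DMSO replicate 1 (adjusted p = 0.19), dTAG-13 replicate 1 (0.44) or dTAG-13 replicate 2 (0.058). CEBPE lost its call at 6 h without DMSO replicate 2 (0.13), ZNF521 without DMSO replicate 2 (0.054) or dTAG-13 replicate 1 (0.11), and C10orf107 without DMSO replicate 1 (0.19), DMSO replicate 2 (0.14) or dTAG-13 replicate 1 (0.49). TCP11L2, SWI5, PRR5, CD34, CD40LG and MYCN at 8 h were lost with any of the 4 libraries left out (highest adjusted p = 0.3, 0.45, 0.89, 0.41, 0.59 and 0.94), and ALDH1A2 without DMSO replicate 1 (0.34), dTAG-13 replicate 1 (0.12) or dTAG-13 replicate 2 (0.18). MYCN at 8 h was also lost with no robust outlier handling (0.064).

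**Figure D1:**
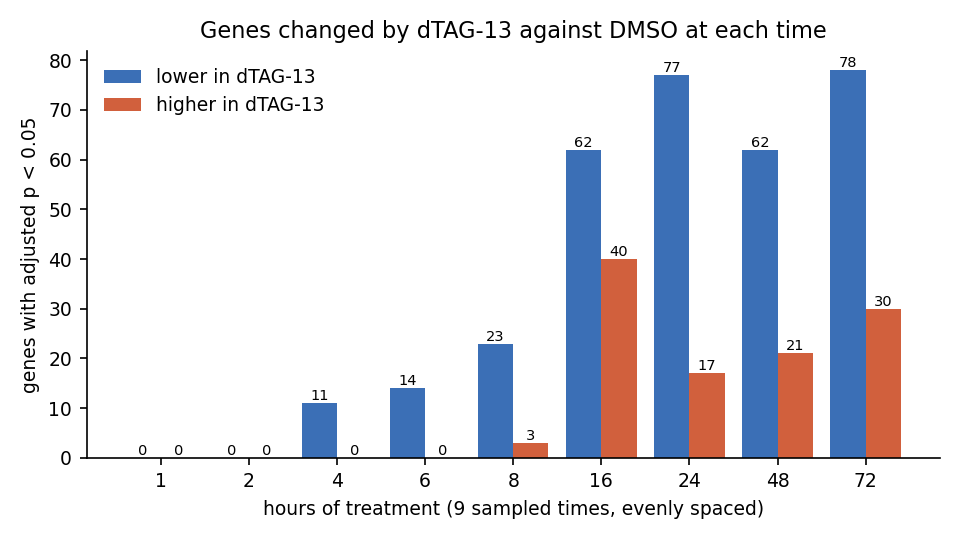
Number of genes lower (blue) and higher (orange) in dTAG-13 than in DMSO at each sampled time, at an adjusted p below 0.05 in edgeR with 2 libraries per group. All groups share a single estimate of spread per gene, so bar heights do not compare the size of the response between times. No bar rises above 0 at 1 h and 2 h, and from 4 h to 72 h lower genes outnumber higher ones, with 78 against 30 at 72 h. Without DMSO replicate 2 this turns at 48 h (96 lower and 107 higher) and narrows at 72 h (77 and 65).

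At 16 h 62 genes were lower and 40 higher. CEBPE fell by 2.6 (SE 0.23, adjusted p = 1.6e-10), from 10.3 ± 0.57 to 1.68 ± 0.18 CPM. Also lower were MYCN (-1.57, SE 0.23, adjusted p = 3.4e-05), STAT5A (-1.14, SE 0.082, adjusted p = 7.6e-13) and ALDH1A2 (-1.05, SE 0.096, adjusted p = 4.5e-08). ERG, an ETS family transcription factor near 1 CPM here, fell by 1.56 (SE 0.38, adjusted p = 0.038). KIAA1462, a gene of cell junctions, fell by 1.19 (SE 0.23, adjusted p = 0.0018). Among the higher genes were ACSS2, which makes acetyl-CoA from acetate (1.42, SE 0.16, adjusted p = 1.5e-06), and UROC1 of histidine breakdown (1.37, SE 0.31, adjusted p = 0.017). FA2H of sphingolipid synthesis (0.83, SE 0.18, adjusted p = 0.013) and the cystine transporter gene SLC7A11 (0.82, SE 0.19, adjusted p = 0.023) rose as well. Called at 16 h and at no other time were 36 higher and 13 lower genes, which does not show that they differ between times. The count of 102 became 58 without DMSO replicate 1 and 43 without dTAG-13 replicate 2. ERG, FA2H and SLC7A11 were lost with any of the 4 libraries left out (highest adjusted p = 0.6, 0.23 and 0.42), UROC1 without DMSO replicate 1 (0.056), DMSO replicate 2 (0.3) or dTAG-13 replicate 1 (0.49), and KIAA1462 without dTAG-13 replicate 2 (0.13).

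Genes of cholesterol synthesis and uptake rose together at 16 h. Of the 16 measured members 11 were higher and 0 lower, and all 16 were higher when adjusted over the list alone, with a median log2 fold change of 0.44 (camera adjusted p = 1.1e-57; adjusted p = 0.00011 with an estimated correlation). HMGCS1, which makes the precursor HMG-CoA, rose by 0.69 (SE 0.13, adjusted p = 0.005) and LSS, the lanosterol synthase, by 0.69 (SE 0.08, adjusted p = 2.7e-07). DHCR7, which completes cholesterol, rose by 0.63 (SE 0.084, adjusted p = 8.1e-06) and FDPS, the farnesyl diphosphate synthase, by 0.58 (SE 0.065, adjusted p = 1e-07). FDPS stood at 232 ± 1.6 CPM in DMSO and 347 ± 5.9 CPM in dTAG-13. The list was also higher at 6 h (median 0.17, 0 members called by edgeR or DESeq2 with 9 at an unadjusted p below 0.05 in each, 6 when adjusted over the list alone, camera adjusted p = 1.7e-14; adjusted p = 0.043 with an estimated correlation). In the 16 h DMSO group the members averaged 7.26 log2 CPM, below the 7.47 to 7.62 of the other 8 DMSO groups, and in the 16 h dTAG-13 group 7.76; these are the 4 libraries that stood apart from the rest. The 11 members became 3 without dTAG-13 replicate 2 (median 0.28) and 5 without DMSO replicate 1 (median 0.36). HMGCS1 lost its call without DMSO replicate 1 (adjusted p = 0.25) or dTAG-13 replicate 2 (0.19), and LSS, DHCR7, FDPS and ACSS2 kept theirs with each of the 4 libraries left out.

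At 24 h 77 genes were lower and 17 higher. CEBPE (-2.74, SE 0.33, adjusted p = 6.8e-07), ERG (-1.82, SE 0.4, adjusted p = 0.012) and MYCN (-1.68, SE 0.29, adjusted p = 0.00072) fell. So did ALDH1A2 (-1.47, SE 0.1, adjusted p = 7.6e-11), the nicotinic receptor gene CHRNA9 (-1.2, SE 0.17, adjusted p = 2.3e-05) and STAT5A (-1.19, SE 0.092, adjusted p = 9.3e-12). SH3TC1 rose by 0.61 (SE 0.089, adjusted p = 3.1e-05) and the metalloprotease gene ADAMTS17 by 0.65 (SE 0.14, adjusted p = 0.024). Larger rises were those of CPA4, a carboxypeptidase (1.49, SE 0.36, adjusted p = 0.036), and RIMBP2 of synapses (1.09, SE 0.25, adjusted p = 0.02). C11orf74 (1.22, SE 0.25, adjusted p = 0.0074) has exons that overlap those of RAG1 or RAG2, so its value is uncertain. The count of 94 became 34 without DMSO replicate 2, 50 without dTAG-13 replicate 1 and 33 without dTAG-13 replicate 2. ADAMTS17, C11orf74 and RIMBP2 were lost without each of these 3 libraries (highest adjusted p = 0.58, 0.56 and 0.68, all without DMSO replicate 2). CPA4 and ERG were lost without DMSO replicate 1 (0.093 and 0.2), DMSO replicate 2 (0.64 and 0.051) or dTAG-13 replicate 2 (0.68 and 0.59), and MYCN without dTAG-13 replicate 1 (0.077). CPA4 was not called by DESeq2 (0.19), with no low-count filter (0.089), with the 4 libraries of that time alone (0.089) or with the replicate number as a block (0.065).

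At 48 h 62 genes were lower and 21 higher. CEBPE (-2.37, SE 0.31, adjusted p = 2.3e-06), ERG (-2.31, SE 0.46, adjusted p = 0.0039), ALDH1A2 (-1.72, SE 0.1, adjusted p = 1.8e-12) and STAT5A (-1.29, SE 0.093, adjusted p = 6.2e-13) fell. So did ADORA1, an adenosine receptor (-1.53, SE 0.37, adjusted p = 0.034), and the complement gene C9 (-1.3, SE 0.29, adjusted p = 0.018). TLE1, a transcriptional corepressor, rose by 0.72 (SE 0.11, adjusted p = 0.00015) and PXN, which encodes the focal adhesion protein paxillin, by 0.63 (SE 0.09, adjusted p = 2.3e-05). The glutamate receptor family gene GRID1 (0.7), ADAMTS17 (0.62) and the retinol transporter gene STRA6 (0.57) were also called. The count of 83 became 203 without DMSO replicate 2, with 96 lower and 107 higher, and 34 without dTAG-13 replicate 1, with 28 lower and 6 higher; replicates of the 48 h DMSO group were the farthest apart of all groups. Without dTAG-13 replicate 1 the calls of TLE1 (adjusted p = 0.055), GRID1 (1), ADAMTS17 (1), STRA6 (0.76), ERG (0.33) and ADORA1 (0.38) were lost. ADAMTS17 (0.17), GRID1 (0.13) and ADORA1 (0.17) were also lost without DMSO replicate 2, STRA6 (0.45), ERG (0.13), GRID1 (0.078) and C9 (0.18) without DMSO replicate 1, and C9 (0.45) and ADORA1 (0.22) without dTAG-13 replicate 2. ADORA1 was not called by DESeq2 (0.072).

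At 72 h 78 genes were lower and 30 higher. CEBPE fell by 2.88 (SE 0.34, adjusted p = 3.1e-07), from 3.44 ± 0.3 to 0.467 ± 0.38 CPM. Lower too were ERG (-2.26, SE 0.48, adjusted p = 0.0078), MYCN (-1.36, SE 0.28, adjusted p = 0.005) and the chemokine receptor gene CCR4 (-1.45, SE 0.19, adjusted p = 3.2e-06). ALDH1A2 fell by 1.85 (SE 0.1, adjusted p = 6.2e-13), from 258 ± 14 to 71.8 ± 6.2 CPM. STAT5A fell by 1.22 (SE 0.092, adjusted p = 1.8e-12), from 38.7 ± 0.74 to 16.6 ± 1 CPM. SVEP1, an extracellular matrix gene, rose by 1.52 (SE 0.29, adjusted p = 0.0019). TIMP1, an inhibitor of metalloproteases, rose by 0.92 (SE 0.21, adjusted p = 0.017) and SH3TC1 by 0.83 (SE 0.089, adjusted p = 2.5e-08). EOMES, a transcription factor of cytotoxic lymphocytes, rose by 0.76 (SE 0.13, adjusted p = 2e-04) and BTG2, an antiproliferative gene, by 0.66 (SE 0.11, adjusted p = 0.00058). Without DMSO replicate 2 the calls were 77 lower and 65 higher. The count of 108 became 53 without DMSO replicate 1 (42 lower and 11 higher), a fit in which SVEP1 (adjusted p = 0.072), TIMP1 (0.51) and ERG (0.095) lost their calls. TIMP1 (0.22) and ERG (0.05) were also lost without dTAG-13 replicate 2, ERG (0.21) and MYCN (0.27) without dTAG-13 replicate 1, and MYCN (0.054) and BTG2 (0.057) without DMSO replicate 2.

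**Figure D2:**
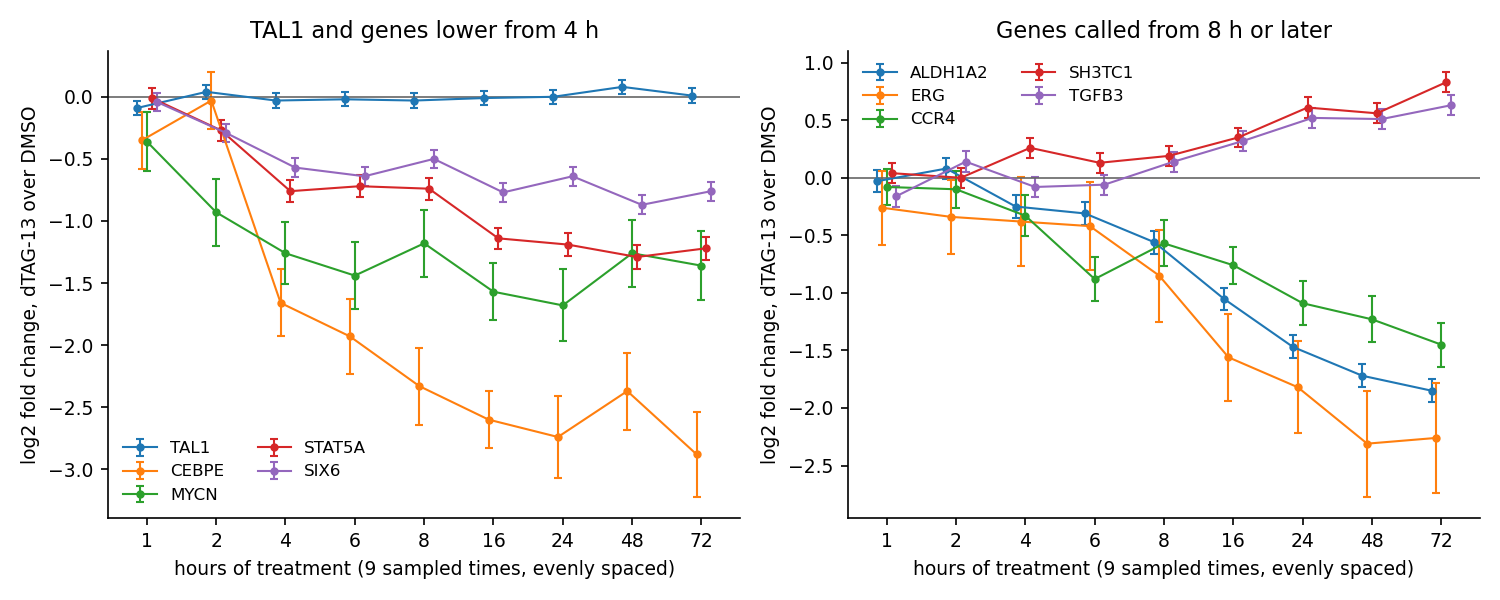
Log2 fold change of dTAG-13 over DMSO (y axis) at the 9 sampled times (x axis, evenly spaced) with its standard error, 2 libraries per group. TAL1 stays between -0.09 and 0.08, CEBPE reaches -2.88 at 72 h, and ALDH1A2 goes from -0.56 at 8 h to -1.85 at 72 h while SH3TC1 and TGFB3 lie at 0.83 and 0.63 at 72 h.

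Over the course 135 genes were lower and 89 higher at 1 or more times, and 0 were called in both directions. Lower at all 7 times from 4 h on were 8 genes, among them CEBPE, MYCN, STAT5A, SIX6, MYB and CYTH1. The last, an exchange factor for small GTPases, lies outside the naming rule and is named because its values were seen. Of the 27 genes lower at 1 or more of 4, 6 and 8 h, 24 were also lower at 72 h. Genes lower at 24, 48 and 72 h numbered 40. Higher at all of 24, 48 and 72 h were 5 genes, among them SH3TC1, TGFB3 (a transforming growth factor beta ligand) and TFDP2 (a partner of E2F factors), the last named because its values were seen. STAT5A and SIX6 kept the call at all 7 times with any 1 of a time's 4 libraries left out. MYCN lost it without 1 or more libraries at each of these times except 16 h (up to 0.94 at 8 h, without dTAG-13 replicate 1), and MYB at 4, 6, 16, 24 and 48 h (up to 0.67 at 4 h, without dTAG-13 replicate 1). CYTH1 lost it at 4 h without any 1 of the 4 (adjusted p up to 0.83, without DMSO replicate 2), at 6 h without DMSO replicate 2 (0.48) or dTAG-13 replicate 1 (0.44), and at 8 h without DMSO replicate 1 (0.072) or dTAG-13 replicate 1 (0.52). SH3TC1 and TGFB3 kept theirs at 24, 48 and 72 h. TFDP2 lost it at 24 h without DMSO replicate 2 (0.44) or dTAG-13 replicate 1 (0.39), at 48 h without DMSO replicate 2 (0.12) or dTAG-13 replicate 1 (0.98), and at 72 h without dTAG-13 replicate 2 (0.074).

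Averaged over the 9 times, with 18 dTAG-13 against 18 DMSO libraries, 272 genes were lower and 183 higher, at a median size of 0.17 on the log2 scale. CEBPE (-1.88, SE 0.096, adjusted p = 1e-18), MYCN (-1.23, SE 0.088, adjusted p = 4.4e-14), ERG (-1.13, SE 0.13, adjusted p = 4.6e-08), STAT5A (-0.82, SE 0.03, adjusted p = 7.1e-24) and ALDH1A2 (-0.79, SE 0.033, adjusted p = 3.7e-17) fell. These are the largest falls that the naming rule allows, which asks for a mean of at least 1 CPM, a fall at 8 or 9 times and no clone name. Falls were also called for CCR4 (-0.72), C10orf107 (-0.58), SIX6 (-0.57), CHRNA9 (-0.57) and LYL1, a close relative of TAL1 (-0.52, SE 0.058, adjusted p = 1.4e-08). Also among the 15 that the rule named were the transporter-like gene SVOPL (-0.73), EPSTI1 (-0.58), IRF5, an interferon regulatory factor (-0.51), and the neuropeptide gene ADCYAP1 (-0.51). All of these fell in each of the 36 fits that left out 1 library.

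The largest average rise that the naming rule allows was that of RAG1 (0.9, SE 0.11, adjusted p = 1.7e-05), and RAG2 rose by 0.42 (SE 0.048, adjusted p = 2.1e-06). Together they encode the recombinase that assembles antigen receptor genes. RAG2 was called by DESeq2 at 16, 24, 48 and 72 h (0.013 to 0.03) and at no single time by edgeR in the fit used for the counts above. With the replicate number as a block edgeR called it at 4, 6, 16, 24, 48 and 72 h (1.7e-05 to 0.036). It did so with no low-count filter at 4, 16, 24, 48 and 72 h (3.1e-05 to 0.00042). RAG2 was also called with the 4 libraries alone at 4 and 24 h (0.00025 and 4.8e-05), and with no robust outlier handling at 16, 24 and 72 h (0.032 to 0.046). RAG1 was higher at 9 of 9 times, for example at 34.5 ± 0.068 CPM in DMSO and 75.4 ± 0.89 CPM in dTAG-13 at 16 h, though at no single time was it called by edgeR in the fit of all 36 libraries used for the counts above (adjusted p of 0.053 or more). Other settings did call RAG1 higher. DESeq2 called it at 16 h (0.031), 24 h (0.0016), 48 h (0.0014) and 72 h (0.0064), as did edgeR with the replicate number as a block (8.4e-05 to 0.00071) and with no robust outlier handling (6e-04 to 0.0068). With the 4 libraries of a time alone edgeR called it at 2, 4, 6, 8, 16 and 72 h (5.9e-08 to 0.00053), and with the 1 CPM filter at 24 h (0.046). Replicates of RAG1 lay far apart at 24 h in DMSO (32.6 ± 15 CPM) and at 48 h in dTAG-13 (74.7 ± 45 CPM). C11orf74 (0.54, SE 0.081, adjusted p = 1e-05) shares 321 exonic bases with RAG1 or RAG2, and its value is uncertain. ID3 (0.49, SE 0.066, adjusted p = 7.5e-05) and ID2 (0.41, SE 0.061, adjusted p = 7.1e-06), which encode inhibitors of E proteins, rose as well. FA2H (0.52), SVEP1 (0.58), ADAMTS17 (0.42), the adhesion receptor gene GPR56 (0.48), GALNT9 (0.49), the vesicular transporter gene SLC32A1 (0.47) and CXXC11 (0.39) were also among the 15 rises that the rule named. All of those named here were called in each of the 36 fits that left out 1 library.

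**Figure D3:**
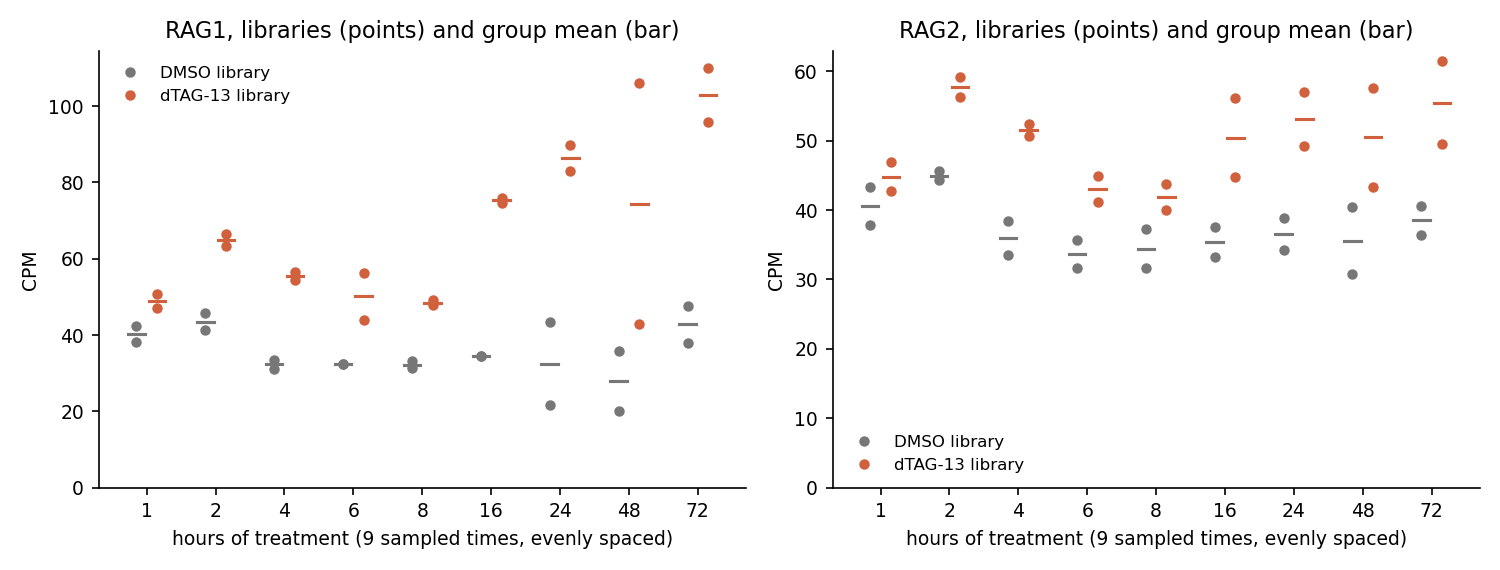
RAG1 and RAG2 in CPM (y axis, from 0) in each library at the 9 sampled times (x axis, evenly spaced), with DMSO in grey, dTAG-13 in orange and the group mean as a bar. At 72 h the means were 42.8 and 103 CPM for RAG1 and 38.5 and 55.5 CPM for RAG2.

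Among the lists tested on the mean of the 9 times, all 7 GIMAP genes fell (7 when adjusted over the list alone, median -0.36, camera adjusted p = 1.3e-71; adjusted p = 1.5e-07 with an estimated correlation). They ran from GIMAP5 at -0.41 (SE 0.023, adjusted p = 8.8e-18) to GIMAP2 at -0.16 (SE 0.027, adjusted p = 9e-05). GIMAP8 (-0.38, adjusted p = 0.022) lost its call in 9 of the 36 fits that left out 1 library, up to 0.072 without DMSO replicate 1 of 8 h. Reported TAL1-activated genes fell, with 4 of 5 lower (4 when adjusted over the list alone), among them ALDH1A2, ARID5B (-0.25, SE 0.031, adjusted p = 6.5e-07) and TRIB2 (-0.11, SE 0.03, adjusted p = 0.024). The camera adjusted p was 3.8e-58, and the adjusted p = 2.3e-09 with an estimated correlation. TRIB2 was lost in 10 of the 36 fits (up to 0.064, without DMSO replicate 2 of 1 h). This list was taken from reports on T-ALL cells, Jurkat among them, and is not independent of the line. Of the 8 measured members of the TAL1 circuit, MYB (-0.3, SE 0.02, adjusted p = 5.7e-15) and RUNX1 (-0.19, SE 0.02, adjusted p = 4.6e-09) fell. The other 6, TAL1 and GATA3 among them, were not called (2 fell when adjusted over the list alone, median -0.01, camera adjusted p = 2.5e-05; adjusted p = 0.012 with an estimated correlation). Of 3 T-ALL oncogenic factors MYCN and LYL1 fell (2 when adjusted over the list alone, camera adjusted p = 2.5e-15; adjusted p = 2.8e-05 with an estimated correlation) and LMO1 was at 0.1 (adjusted p = 0.64).

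Thymocyte differentiation genes were higher as a list on the mean of the 9 times, with 5 of 21 called higher (RAG1, RAG2, CD4 and CD1E among them) and TOX lower. The list held 13 higher and 1 lower when adjusted over the list alone (median 0.06, camera adjusted p = 3e-14; adjusted p = 0.0013 with an estimated correlation). PTCRA, the invariant chain of the pre-T cell receptor, was at 0.44 (SE 0.12, adjusted p = 0.055). At single times PTCRA was called higher at 24 h by DESeq2 (0.025), and at 24 h and 72 h with the replicate number as a block (4.9e-06 and 3.5e-05), with the 4 libraries of a time alone (1.5e-05 and 0.002) and with no robust outlier handling (0.0055 and 0.016). The authors' deposited tables call it at both times too (0.00043 and 9e-04). NOTCH targets were higher, through NOTCH3 (0.29, SE 0.032, adjusted p = 3.5e-08), IL7R (0.25, SE 0.033, adjusted p = 1.5e-06) and MYC (0.11, SE 0.023, adjusted p = 0.0029), while DTX1 fell by 0.16. In numbers these were 3 higher and 1 lower of 12, and 4 and 1 when adjusted over the list alone (camera adjusted p = 0.00058; adjusted p = 0.018 with an estimated correlation). E proteins and related factors, 12 measured, held 3 higher genes (ID1, ID2 and ID3) and 1 lower (LYL1), and the same numbers when adjusted over the list alone (camera adjusted p = 0.025; adjusted p = 0.042 with an estimated correlation). ID1 (0.32, adjusted p = 0.047) was lost in 27 of the 36 fits that left out 1 library (up to 0.096, without DMSO replicate 2 of 4 h), by library size alone (0.053) and with no low-count filter (0.07). The BCL2 family, 14 measured, was higher through BMF (0.24, SE 0.032, adjusted p = 9.7e-07) and BCL2L11 (0.17, SE 0.028, adjusted p = 4.4e-05), which promote cell death; BCL2L11 overlaps MIR4435-1HG, so its value is uncertain. It held 4 higher genes when adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.0065 with an estimated correlation). Cholesterol synthesis held 7 higher genes of 16 on this mean (12 when adjusted over the list alone, median 0.1, camera adjusted p = 2.6e-15; adjusted p = 0.012 with an estimated correlation). The retinoic acid pathway, 11 measured, fell through ALDH1A2, with STRA6 higher, also when adjusted over the list alone (median -0.02, camera adjusted p = 2.4e-05; adjusted p = 0.0011 with an estimated correlation).

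**Figure D4:**
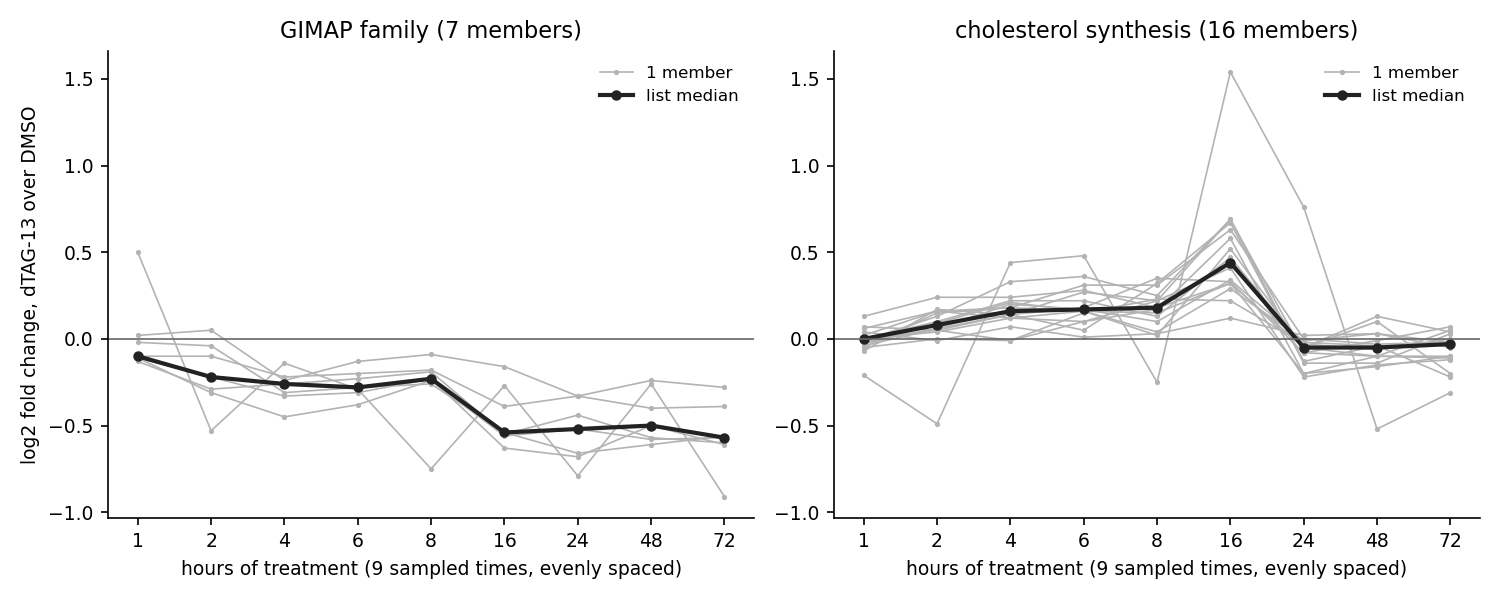
Log2 fold change of dTAG-13 over DMSO (y axis) for each measured member (grey) and the list median (black) at the 9 sampled times (x axis, evenly spaced), for 7 GIMAP genes and 16 cholesterol synthesis genes. The GIMAP median lies at -0.54 at 16 h and -0.57 at 72 h, and the cholesterol median reaches 0.44 at 16 h.

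Several lists were called on the mean only with the preset correlation. S phase genes held E2F2 (0.22, SE 0.023, adjusted p = 3.6e-09) and UHRF1 higher of 25 (2 when adjusted over the list alone, camera adjusted p = 0.0039; adjusted p = 0.13 with an estimated correlation). G2 and mitosis genes held the kinase gene TTK higher of 22 (1 when adjusted over the list alone, camera adjusted p = 0.045; adjusted p = 0.56 with an estimated correlation). Homing and cytokine receptors, 16 measured, held 4 lower genes, CCR4, S1PR1 and IL2RG among them, and CXCR4 and IL7R higher (6 lower and 3 higher when adjusted over the list alone, camera adjusted p = 0.018; adjusted p = 0.13 with an estimated correlation).

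Other lists were not called on the mean. The T cell receptor complex (20 genes, adjusted p = 0.46) held LCP2 (-0.17) and CD28 (-0.14) lower and PTPN22 and CD247 higher, the same numbers when adjusted over the list alone. MYC targets (21 genes, 0.87) held MYC itself higher, with TFRC lower as well when adjusted over the list alone. The p53 targets (20 genes, 0.86) held CDKN1A (0.38) and BTG2 (0.25) higher, 3 higher when adjusted over the list alone, with a median of -0.02 and a mean of 0.01. Immediate early genes (16 genes, 0.86) held DUSP2 higher and CD69 (-0.33) and ATF3 (-0.17) lower, 2 and 3 when adjusted over the list alone, with a median of 0.02 and a mean of -0.04. Integrated stress and unfolded protein response genes (18 genes, 0.055) held XBP1 (0.13) higher and ATF3 lower, 3 and 1 when adjusted over the list alone. Camera did call this list with the replicate number as a block (adjusted p = 0.018). Interferon response genes (18 genes, 0.53) held XAF1 (-0.11) lower, 1 when adjusted over the list alone, and the erythroid and megakaryocyte markers (9 genes, 0.24) held NFE2 lower, a gene under 1 CPM in most groups, also 1 when adjusted over the list alone. NK and cytotoxic markers (7 genes, 0.53) held GZMA (-0.37) lower and EOMES (0.16) higher, 1 lower and 2 higher when adjusted over the list alone. The cereblon list (12 genes, 0.46) held ZNF692 (0.17) higher and the FKBP family (7 genes, 0.65) FKBP5 (0.09), each 1 when adjusted over the list alone, and the FKBP median was -0.01 against a mean of 0.02. With 1 of the 36 libraries left out, some of these calls and of those above were lost: PTPN22 in 23 fits (up to 0.1, without DMSO replicate 1 of 2 h), STRA6 in 20 (0.15, without dTAG-13 replicate 2 of 24 h) and EOMES in 5 (0.065, without dTAG-13 replicate 1 of 8 h). UHRF1 was lost in 2 (0.058, without dTAG-13 replicate 2 of 24 h), TTK in 1 (0.056, without dTAG-13 replicate 1 of 48 h) and XAF1 in 1 (0.051, without DMSO replicate 2 of 24 h). PTPN22 was also lost with no low-count filter (0.11) and STRA6 with DESeq2 (0.061). NFE2 was lost in most of these fits (up to 0.22, without DMSO replicate 1 of 2 h) and by library size alone (0.052).

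No member of 7 further lists was called by edgeR on the mean: NF-kB targets (13 genes, adjusted p = 0.54), heat shock (13 genes, 0.47), glycolysis and hypoxia (20 genes, 0.88), B cell markers (6 genes, 0.65), ribosomal proteins (85 genes, 0.53), replication-dependent histones (16 genes, 0.94) and mitochondrial mRNAs (13 genes, 0.69). At an unadjusted p below 0.05 these 7 lists held 2, 1, 2, 2, 0, 0 and 0 genes, and DESeq2 called 0 in each (2, 2, 2, 2, 0, 0 and 0 unadjusted). When adjusted over the list alone, EGLN3 was higher among the glycolysis and hypoxia genes, BLNK and POU2AF1 were lower among the B cell markers, whose median of 0.02 and mean of -0.08 differ in sign, and the other 5 lists held 0. Over the 270 tests of 30 lists at 9 times camera called 72, and 21 of these were kept with an estimated correlation. These 21 were reported TAL1-activated genes at all 7 times from 4 h, GIMAP genes at 4, 6, 16, 24, 48 and 72 h, T-ALL oncogenic factors at 4, 6 and 16 h, cholesterol synthesis at 6 and 16 h, and the retinoic acid pathway at 16, 24 and 48 h. Among those not kept were ribosomal proteins at 4, 8, 16, 48 and 72 h (camera adjusted p = 4.1e-19, 3e-11, 0.028, 5.7e-06 and 8.8e-06). Mitochondrial mRNAs at 16 h (0.00014), heat shock at 24 h (0.031) and glycolysis and hypoxia at 4 h (0.023) were not kept either. Ribosomal proteins and mitochondrial mRNAs were set as checks on library composition and RNA quality. No member of these lists was called by edgeR at these times.

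The late response, the mean of 24, 48 and 72 h, was set against the early one, the mean of 2, 4, 6 and 8 h, to separate early from later changes. In this test 53 genes were lower and 13 higher late than early. The early mean includes 2 h, when no gene was called. In the authors' deposited tables CEBPE stood at -0.03 at 2 h and -1.67 at 4 h. A gene that fell by 4 h and then stayed level can therefore also appear lower late than early. ALDH1A2 had the difference with the lowest p (-1.42, SE 0.075, adjusted p = 2.5e-13). ERG (-1.64, SE 0.33, adjusted p = 0.0064), CEBPE (-1.18, SE 0.26, adjusted p = 0.016), EPSTI1 (-0.89, SE 0.15, adjusted p = 0.00074) and the serine protease inhibitor gene SPINK2 (-0.82) were lower late than early. So were CCR4 (-0.79, SE 0.15, adjusted p = 0.0022), the surrogate light chain gene IGLL1 (-0.76, SE 0.097, adjusted p = 0.00024) and CHRNA9 (-0.75, SE 0.12, adjusted p = 0.00052). STAT5A differed by -0.61 (adjusted p = 2.2e-07). Higher late than early were TIMP1 (0.78, SE 0.16, adjusted p = 0.01), SH3TC1 and TGFB3 (0.52 each, SE 0.067, adjusted p = 4.5e-06), and PXN (0.4, SE 0.07, adjusted p = 0.00091). TLE1 (0.38), IPCEF1 (0.42), DCLK3 (0.33) and MIR4435-1HG (0.42) were too, the last a noncoding RNA that overlaps BCL2L11 and is uncertain. MYCN (-0.23, adjusted p = 0.9), MYB (-0.06, adjusted p = 0.84) and LYL1 (0.01, adjusted p = 1) were not called.

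By list, GIMAP genes were lower late than early (3 of 7, 6 when adjusted over the list alone, camera adjusted p = 1e-14; adjusted p = 0.0037 with an estimated correlation). TAL1-activated genes were lower late as well (2 of 5, ALDH1A2 among them, also when adjusted over the list alone, 4.4e-18; adjusted p = 2e-05 with an estimated correlation), and so were cholesterol synthesis genes (4 of 16, 12 when adjusted over the list alone, median -0.21, 5e-21; adjusted p = 0.0048 with an estimated correlation). Over the 36 fits that left out 1 library, SPINK2 lost its late call in 24, TLE1 in 15 and DCLK3 in 30 (adjusted p up to 0.12, 0.12 and 0.21, each without dTAG-13 replicate 1 of 48 h). IPCEF1 lost it in 21 (up to 0.15, without DMSO replicate 1 of 24 h), MIR4435-1HG in 4 (up to 0.084, without DMSO replicate 2 of 24 h) and CEBPE in 4 (up to 0.11, without dTAG-13 replicate 1 of 72 h). DCLK3 (0.056) and IPCEF1 (0.051) were also lost with no robust outlier handling.

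The response of 49 genes differed between the 9 times in the interaction test, among them ALDH1A2 (adjusted p = 3.4e-11), STAT5A (5.1e-10), ZNF521 (8.5e-08), CEBPE (6.3e-07), FDPS (7.8e-06) and SIX6 (2.8e-05). Since 1 h and 2 h are among these times, a fall that began by 4 h and then stayed level can also be called. MYCN (adjusted p = 1) and MYB (0.32) were not called, although both were lower at all 7 times from 4 h. RAG1 (adjusted p = 1) was not called either. With DESeq2 the count was 80 and with no low-count filter 164, and without the 16 h libraries it was 35.

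Lower genes recurred between times. All 11 genes lower at 4 h were lower at 16 h, where 0.041 are expected from independent lists, 22 of the 23 lower at 8 h were lower at 72 h (0.11 expected), and 50 genes were lower at both 24 h and 72 h (0.36 expected). Of the higher genes, 7 were shared by 24 h and 72 h (0.03 expected), and 4 of the 40 at 16 h were shared with 24 h (0.04 expected). The lists are not independent, because the spread of each gene was estimated once for all times. A gene of low spread is more easily called at every time, so the expected numbers are too low as a reference. Across all 16834 genes, which are not independent replicates, the log2 fold changes of 2 times correlated little, with a median Pearson's r of 0.02 over 36 pairs of times (-0.03 to 0.14), and 0.13 over the 9482 genes of at least 10 CPM (-0.19 to 0.53).

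The authors' deposited comparisons give an adjusted p below 0.05 to 0, 2, 17, 22, 26, 72, 57, 25 and 45 genes from 1 h to 72 h, of which 0, 2, 5, 8, 5, 32, 13, 5 and 13 are higher, against 0 higher here at 1, 2, 4 and 6 h. Genes with a deposited adjusted p number 5747 at 4 h and 7776 at 6 h, and 13381 to 28638 at the other times. STAT5A, CEBPE and MYCN have none at 4 h, nor do CEBPE and MYCN at 6 h, so these could not be called there. The 2 genes of the authors' deposited table at 2 h are RAG1 (0.58, SE 0.1, adjusted p = 0.00051) and MSMO1 (0.36, SE 0.07, adjusted p = 0.0022), named because their values were seen. The deposited tables also call RAG1 higher at 4, 6, 8, 16 and 72 h (1.2e-08, 0.0012, 0.00073, 1.8e-22 and 3.2e-18), but not at 24 h (0.39) or 48 h. RAG2 is called higher in them at 4, 16, 24 and 72 h (0.0033, 0.029, 0.0027 and 0.046). CD40LG is called lower at 4, 6 and 8 h (1.8e-06, 6e-09 and 3e-10), while its first call here was at 8 h. Of the genes called in the deposited tables, 7 at 4 h, 9 at 6 h, 18 at 8 h, 62 at 16 h, 49 at 24 h, 24 at 48 h and 39 at 72 h were also called here, all in the same direction. The log2 fold changes of the 2 sources correlated at 0.999 to 1 across genes at each time.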

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

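The tests of a single library, of the DMSO level and of 16 h against the other times were chosen only after the result was seen; the splits were planned. What brought these results here is a response to dTAG-13 that differed between times in the interaction test, which called 49 genes. Among genes named here, the adjusted p was 3.4e-11 for ALDH1A2, 4.3e-10 for TSPAN7, 5.1e-10 for STAT5A, 8.5e-08 for ZNF521, 6.3e-07 for CEBPE, 2.8e-05 for SIX6, 6.6e-05 for TGFB3, 0.00013 for SH3TC1, 0.00039 for CYTH1, 0.00082 for DTX1, 0.0013 for CD34, 0.0022 for CCR4, 0.0032 for IGLL1, 0.007 each for PXN and C10orf107, 0.0071 for CHRNA9, 0.014 for GIMAP4, 0.015 for EPSTI1, 0.017 each for GIMAP5 and GIMAP1, 0.026 for TIMP1 and 0.038 for TFDP2. Other named genes that differed were FDPS (7.8e-06), ACAT2 (6.3e-05), TMEM97 (1e-04), ACSS2 (0.00058), IDI1 (0.0014), LSS (0.0017), SQLE (0.0087), DHCR7 (0.016) and INSIG1 (0.025).

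Each time's 4 libraries were split into 2 against 2 in 100 ways, the real one included. Of these, 2 gave as many genes with a response that differed between times. The splits mix the treatments within a time, which undoes the treatment effect itself as well as its differences between times. They therefore cannot decide whether those differences are chance. The real split gave 49 and the highest other 81; that split kept treated and untreated libraries apart at 6 of the 9 times, 24, 48 and 72 h among them. For the late minus early difference 2 of the 100 gave as many genes (real 66, highest other 143, a split that kept the treatments apart at 4 times, with 24, 48 and 72 h among them), and for the mean over the 9 times 1 of the 100, the real one (455, highest other 14). For the mean, none of the other splits came near the real count. This excludes chance only if the 4 libraries of a time vary independently. The labels do not say whether replicates were separate cultures, and 2 libraries of the same culture would favour the real split. For late minus early the splits cannot decide, because they undo the treatment effect itself as well.

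The log2 fold change of dTAG-13 over DMSO in cholesterol synthesis genes was higher at 16 h than on the mean of the other 8 times (median difference 0.39, adjusted p = 0.00015 with an estimated correlation). The tables argue against 1 deviating library as the whole cause, since the median of the 16 members was lowest, at 0.28, without dTAG-13 replicate 2 and stayed above 0 without any of the 4. Lower sterol genes in the 16 h DMSO cultures may contribute, since their mean log2 CPM there lay below the lowest of the other 8 DMSO groups (difference -0.2, against at most 0.12 between DMSO replicates). The 2 dTAG-13 libraries of 16 h differed by 0.25 on the same measure, which is more than this shift. A response to dTAG-13 at 16 h also stays open. In the dTAG-13 groups of 2, 4, 6 and 8 h the mean of 7.57, 7.68, 7.71 and 7.62 lay above the 7.5, 7.5, 7.52 and 7.47 of their DMSO groups. At 1, 24, 48 and 72 h it was 7.51, 7.49, 7.51 and 7.56, below the 7.52, 7.53, 7.58 and 7.62 of DMSO. A lower DMSO level and a response to dTAG-13 cannot be told apart, because the 4 libraries of 16 h stand apart as a set and no other set was sampled at that time.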

How the results depend on the processing

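With 2 libraries per group, and in leave-one-out fits a lone library that is assumed to vary like the other groups, the calls at single times rest on few libraries; of 234 called values of named genes and list members 132 were kept in each leave-one-out fit of their comparison and 102 lost in 1 or more. Depth limits genes near 1 CPM, such as ERG, NFE2 and CEBPE in dTAG-13. No called value of a named gene changed sign. The fits with no robust outlier handling, those without the 16 h libraries, the list tests by library size and with 1 library left out, and the correlation between times with 1 library left out were chosen after seeing the data. Where values differ the cause was not tested. A fit on 4 libraries has 2 residual degrees of freedom and 18 are left with all 36. The fit of all 36 also uses a single spread per gene for all groups. Replicates were farther apart in some groups than in others. The chi-square per degree of freedom was 10.5 at 48 h and 8.25 at 72 h in DMSO, and 3.59 at 8 h in dTAG-13. Counts of calls at different times therefore do not compare the size of the response.

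The count on the mean stayed within 1.5 times of 455 in each alternative: 445 with DESeq2 size factors, 436 by library size, 462 with no filter, 455 with the 1 CPM filter, 440 with DESeq2 and 338 without the 16 h libraries. Scaling moved the median of all genes by at most 0.02 in log2 fold change. With no filter the counts were 2 at 2 h, 17 at 4 h, 28 at 6 h, 49 at 8 h, 180 at 72 h, 103 for late minus early and 164 for the interaction. With the 4 libraries of that time alone they were 1, 3, 24, 34, 61, 63, 20 and 42 at 1, 2, 4, 6, 8, 16, 48 and 72 h, and of 182 values of named genes and list members at single times 41 lost their call and 10 gained one. These counts exceed those of the fit of all 36 libraries at 4, 6 and 8 h (11, 14 and 26). They lie below them at 16, 48 and 72 h (102, 83 and 108). DESeq2 gave 24 at 6 h and 80 for the interaction. List calls numbered 72 by camera with the preset correlation, 21 with an estimated correlation and 36 by fry. The median correlation between times was 0.025 over all genes and 0.134 over genes of at least 10 CPM.

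Replicate numbers were checked for pairing by the correlation of deviations of libraries with the same number. It was above 0.1 at 5 of the 9 times, with 0.49 at 16 h, 0.39 at 72 h, 0.28 at 6 h, 0.2 at 2 h and 0.18 at 4 h. At 24, 8 and 1 h it was 0.08, 0.02 and 0.01, and at 48 h -0.18. The main fit did not take the numbers as pairs, so it may ignore a pairing at some times. Whether the numbers mark a shared day is not known. At 16 h and 72 h, where the correlation was highest, the main fit called 102 and 108 genes. With the replicate block the counts were 1 at 2 h (ID3, chosen after its value was seen), 25 at 6 h, 42 at 8 h, 163 at 16 h, 183 at 72 h, 531 on the mean, 107 for late minus early, 78 for the interaction and 85 for the lists.

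With 1 library left out the counts ran from 0 to 0 at 1 h and 2 h, 2 to 5 at 4 h, 5 to 10 at 6 h, 7 to 18 at 8 h, 43 to 78 at 16 h, 33 to 78 at 24 h, 34 to 203 at 48 h, 53 to 142 at 72 h, 380 to 461 on the mean, 48 to 87 for late minus early, 41 to 57 for the interaction and 67 to 78 for the lists, and the correlation between times from 0.017 to 0.026.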

Other observations

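Tests of a single library, of reads of C11orf74 in RAG1 and RAG2, and of neighbouring genes were chosen only after the result was seen, and every gene in this and the next paragraph was chosen after its values were seen. No list of fatty acid synthesis genes was tested. At 16 h some single genes of it were higher: FASN, the fatty acid synthase, by 0.51 (SE 0.076, adjusted p = 4.2e-05), from 341 ± 3.6 to 484 ± 24 CPM (n = 2), ELOVL6, an elongase, by 0.53 (SE 0.088, adjusted p = 0.00023) and FADS2, a desaturase, by 0.37 (SE 0.059, adjusted p = 7.9e-05). SCD, which makes monounsaturated fatty acids, was higher by 0.6 (SE 0.099, adjusted p = 0.00074), ACLY, which makes cytosolic acetyl-CoA, by 0.38 (SE 0.065, adjusted p = 0.00027) and ACACA, which makes malonyl-CoA, by 0.33 (SE 0.077, adjusted p = 0.026). ACAT2 (0.56, adjusted p = 1.5e-06) and TMEM97 (0.55, adjusted p = 5e-06), a sterol enzyme and a sterol-regulated receptor, were higher too. FASN, ELOVL6, FADS2, ACAT2 and TMEM97 kept the call with each of the 4 libraries left out, while SCD lost it without DMSO replicate 1 (0.079) or dTAG-13 replicate 2 (0.09), ACLY without dTAG-13 replicate 2 (0.24) and ACACA without any one of the 4 (up to 0.37). With the 4 libraries of that time fitted alone SCD (0.59), ACLY (0.062) and ACACA (0.072) were not called.

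STAT5B and STAT3, which like STAT5A relay cytokine signals, fell on the mean of the 9 times by 0.25 (SE 0.021, adjusted p = 6.7e-12) and 0.2 (SE 0.02, adjusted p = 1e-09); STAT3 lies next to STAT5A, and reads shared between the paralogs STAT5A and STAT5B were not examined. TSPAN7, a tetraspanin, fell by 0.39 (SE 0.02, adjusted p = 1e-18) and at 72 h by 0.72 (adjusted p = 1.9e-11), from 276 ± 3.1 to 167 ± 5.2 CPM. CYTH1 fell by 0.36 (SE 0.021, adjusted p = 1.1e-16), RHOH, a GTPase of blood cells, by 0.2 (SE 0.023, adjusted p = 6.8e-08) and ETV6, an ETS family repressor, by 0.15 (SE 0.02, adjusted p = 6.5e-07). Each of these 6 kept the call on the mean in all 36 fits that left out 1 library.

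RAG1 and RAG2 rose together on the mean of the 9 times, and C11orf74 next to them did too. The tables argue against 1 deviating library, since the highest adjusted p of either gene with 1 library left out was 6.1e-05, and against the 2 times with replicates far apart, since the mean without 24 h and 48 h had an adjusted p of 0.0011 for RAG1 and 7.9e-05 for RAG2. Reads counted to C11orf74 were few, at most 5.03 CPM in a library against a mean rise of 12.5 CPM in RAG2 and 32.1 CPM in RAG1. That figure leaves out any reads of C11orf74 transcripts that were counted to RAG1 or RAG2, so it cannot decide whether they contribute. The rise of C11orf74 itself may come from reads of RAG1 or RAG2, with which it shares 321 exonic bases in GENCODE v29. A response of the RAG locus to loss of TAL1 stays a hypothesis found and tested on the same data.

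Neighbouring genes tended to fall together. Among 277 genes lower at 1 or more times or on the mean, 38 pairs were adjacent among the 16235 placed genes, and 25 without pairs that overlap or whose names begin with the same letters (at least 3), where 10000 permutations of the calls gave a mean of 3.45 and at most 11 (p = 1e-04, the smallest they can give). Without 2 genes of 1 clone name or with 1 symbol that begins the other, left out in addition after the pairs were seen, 22 pairs remained against a mean of 3.38 and at most 11. Such pairs were C10orf107 (-0.58) with ARID5B (-0.25), ATF3 (-0.17) with BATF3 (-0.17), SOX4 (-0.13) with CASC15 (-0.16), and CEBPE (-1.88) with C14orf119 (-0.19) and with SLC7A8 (-1.33, mean below 1 CPM). The permutations drew genes without regard to their expression. Runs of adjacent genes count as more than 1 pair, so the pairs are not independent and the p may be too small. Elements shared by neighbours may respond to loss of TAL1, and unannotated transcripts that run across 2 genes stay open as well, since reads between genes were not available. For higher genes 5 such pairs were found against a permutation mean of 2.07 (p = 0.0574), which leaves the question open.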
